A study of Mus musculus with 107 samples.

How the data were processed

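Total RNA (10 µg) from 8 mm ear skin biopsies was labelled and hybridized to a pair of Affymetrix mouse arrays, called array A and array B. Per the labels, the authors computed probe set signals with MAS5; its version, scaling target and background settings are not given. The deposited values are intensity signals on a linear scale. Each ear was measured once on array A, and ears of the mustard series also once on array B. No scaling between arrays is visible: their 2% trimmed means differed by 4.03 times on array A and 2.77 times on array B. Arrays give no depth, and the number of ears limits the precision.

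Groups were read from the treatment labels. Doses were 0.08 mg (0.5 µmol) of mustard, 6.25 mg (50.3 µmol) of dimercaprol and 1.34 mg (3.74 µmol) of indomethacin. For octylhomovanillamide the treatment label gives 0.6 mg and the protocol 0.585 mg (1.995 µmol). Volumes were 10 µL for dimercaprol, 20 µL for indomethacin and 30 µL for octylhomovanillamide. The drugs differed in dose and volume, so that differences between them are differences between treatments at those doses. Ears with mustard alone are labelled without a pretreatment. Comparisons of pretreated ears with mustard ears therefore hold a drug together with its ethanol, and these cannot be told apart.

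Each array was scaled to a 2% trimmed mean of 500, and log2 of the scaled signal plus 16 was analysed. Probe sets with a mean scaled signal of at least 100 were kept, 15953 of 22690 on array A (9611 genes) and 17287 of 22575 on array B (8094 genes). The arrays were analysed apart. Linear models were fitted with limma 3.58.1 (lmFit, and eBayes with trend) in R 4.3.3, with the data.table package (1.17.8). P-values were 2-sided and Benjamini-Hochberg adjusted over the probe sets kept, with a threshold of 0.05. The mustard and methylene chloride groups with the drug-then-mustard groups shared 1 fit, and the animals without mustard another, with the naive ears of an animal averaged. Differences of differences and methylene chloride against naive used all array A ears. Left ears were compared with a limma F-test.

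Genes named in each comparison follow a rule. Of genes past the threshold with every treated ear on the same side of the control mean, the 8 largest rises and 8 largest falls of array A and the 3 and 3 of array B were eligible. To these came up to 4 members of each list with the smallest adjusted p, and a panel of 20 skin response genes, of which Il6 was not measured. Predicted genes known only by an accession or clone were skipped in the ranking. Each gene was represented by its kept probe set with the highest mean log2 value. For differences of differences, the 8 largest called rises and falls were eligible without the condition on single ears. Which eligible genes are named was chosen after the results were seen. Cdh13, Igfbp3, Epgn, Slc6a4, Krt17 and Ankrd44 were added as examples after the alternatives had been run. They were added as steadier in their calls than certain genes named first, which are kept beside them. Ankrd44 was not steadier than Frk, which kept its call when each ear was left out in turn.

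The 35 gene lists were tested with limma camera at a preset correlation of 0.01 and adjusted over the lists of a comparison; the estimated correlation was an alternative. The B cell (3 measured genes) and red blood cell (2 measured genes) lists were too small to test, leaving 33. Lists overlap, and several hold genes made by more than 1 cell type of skin. The mustard signature score of an ear was the mean over risen minus the mean over fallen signature probe sets, divided by 2, of its log2 value minus the methylene chloride mean. Signatures were derived 5 times, each without 1 mustard animal, from probe sets past the threshold with at least a 2-fold change. A mustard ear was scored with the signature derived without its animal. Scores were compared by 2-sided exact permutation tests, adjusted over the 3 drugs; 462 splits allow a smallest p of 0.00216 and 252 splits of 5 and 5 ears one of 0.00794.

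Samples, groups, tests, lists, named-gene rule and most alternatives were fixed before the data were examined. The alternatives were values without rescaling, quantile normalization, a pseudocount of 64 or a floor at 16, no filter or a minimum of 300, eBayes without trend, the animal as a random or fixed block, the skeletal muscle mean or the log2 ratio of 3' to 5' Gapdh probe sets as a covariate, the mean over all kept probe sets of a gene for lists, a signature without the 2-fold threshold, and leaving out each ear. Added after seeing the data were array brightness as a covariate, scaling on the 100 probe sets shared by both arrays, and leaving out mustard ears 5 and 37 or methylene chloride ear 19. Labels give left and right ears of an animal the same number. Over 17 pairs on array A, the ears of an animal correlated on average at 0.164 (from −0.0943 to 0.439) across genes after removal of group means, against −0.00808 for ears of different animals, and the consensus correlation was 0.133 on array A and 0.0728 on array B.

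The procedure was tested on simulated data, drawn from normal distributions with the mean and residual SD of each probe set and with known changes added. Simulated genes were independent of each other, so the error rate of the list test on correlated genes was not tested. All groups were also given the same SD of a probe set. Measured spreads could differ: Slc6a2 on array B had a log2 SD of 1.85 in mustard ears and 0.33 in control ears. Error rates with such unequal spreads were not tested. Where the smaller group spreads more, the pooled SEs and p-values may be too small. For mustard against methylene chloride on array A, 59.7%, 92.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered. For ethanol against naive ears it was 4.48%, 64.2% and 92.4%, and false calls were 3.39% to 8.26% of calls over the comparisons tested. The list test called 1 of 1 changed and 0 of 19 unchanged lists, and the score gave 50.6% where 50% was added.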

Results

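RNA was measured in mouse ear skin 24 h after exposure to sulfur mustard, an alkylating agent that blisters skin and damages DNA. Each mustard animal had 0.08 mg of mustard in 5 µL of methylene chloride on the right ear and methylene chloride alone on the left. Further animals were given a drug in ethanol 15 min before mustard. The drugs were dimercaprol, a dithiol that binds metals and electrophiles, indomethacin, which inhibits cyclooxygenases, and octylhomovanillamide, a capsaicin analog. Array A and array B, a pair of Affymetrix mouse arrays, were each hybridized with 21 methylene chloride left ears. They were also hybridized with 5 ears given mustard alone, 6 given dimercaprol, 6 given indomethacin and 5 given octylhomovanillamide before mustard. Array A alone held a separately numbered set of animals without mustard. These gave 5 naive ears of 3 animals, 3 ethanol ears, 4 dimercaprol ears, 4 indomethacin ears and 5 octylhomovanillamide ears. The trimmed mean signal of the 64 array A arrays ran from 66.3 to 267, and that of the 43 array B arrays from 18.7 to 51.7. Arrays give no counts, so the number of ears limits the precision.

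The comparison of mustard ears with methylene chloride ears asked how skin had responded after 24 h. On array A the largest rises included genes of stressed and wound-edge keratinocytes. Krt6b, a keratin of activated epidermis, rose by a log2 fold of 6.43 ± 0.61 (SE; 5 mustard ears, 21 control ears; adjusted p = 5.99e-11), an 86.4-fold change. Its scaled signal was 20477 ± 8295 (SD) in mustard ears and 297 ± 347 in control ears. The partner keratin Krt16 rose by 5.64 ± 0.47, the antimicrobial peptide Defb3 by 6.59 ± 0.59, and the cornified envelope genes Lce3a, Sprr2f and Lce3c by 5.90 ± 0.53, 5.35 ± 0.49 and 5.30 ± 0.52. S100a8 and S100a9, which form calprotectin, rose by 5.70 ± 0.53 and 5.45 ± 0.53. Among the falls, Mycl, a Myc family transcription factor, changed by -2.78 ± 0.35, and Mt4, the metallothionein of stratified epithelium, by -2.78 ± 0.34. The serotonin transporter Slc6a4 changed by -2.75 ± 0.31 and Dym by -2.37 ± 0.27. The chondroitin sulfotransferase Chst15 changed by -2.34 ± 0.27, Clca3a2 by -2.26 ± 0.29, Gas1 by -2.23 ± 0.27 and the Wnt antagonist Dkk2 by -2.21 ± 0.24. For each of these 16 genes, all 5 mustard ears lay on the same side of the control mean, as the rule of selection required. Mean scaled signals were under 100 in control ears for Defb3, Lce3a and Sprr2f and in mustard ears for Slc6a4, Dym, Chst15 and Dkk2, so the size of these folds depends on the pseudocount. With 64 in place of 16, Defb3 stood at 5.30 and Dkk2 at −1.40.

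Of the 33 gene lists tested, 8 were called between mustard and methylene chloride ears. Among wound and stress keratinocyte genes, 17 of 19 rose and 0 fell (18 rose and 0 fell adjusted over the list alone), with a median log2 fold of 3.45 (camera adjusted p = 4.23e-16, and 0.113 with an estimated correlation). Among p53 targets and DNA damage genes, 17 of 23 rose and 3 fell (18 rose and 3 fell adjusted over the list alone, camera adjusted p = 4.23e-11, and 0.0147 with an estimated correlation), and this was the single list whose call held with an estimated correlation. The p53 inhibitor Mdm2 rose by 1.95 ± 0.19, the cell cycle inhibitor Cdkn1a by 1.92 ± 0.14, Ccng1 by 1.92 ± 0.14 and the kinase Plk2 by 2.37 ± 0.18. Among neutrophil markers, 8 of 13 rose and 1 fell (9 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000274, and 0.197 with an estimated correlation), including Lcn2 at 3.60 ± 0.32; S100a8 and S100a9 belong to this list and are also made by keratinocytes. Among acute cytokines and chemokines, 8 of 12 rose and 1 fell (8 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0112, and 0.344 with an estimated correlation). The neutrophil-attracting chemokines Cxcl1 and Cxcl2 rose by 4.58 ± 0.49 and 3.59 ± 0.53, and interleukin 1 beta (Il1b) by 2.38 ± 0.31. The mean scaled signal of Cxcl1 was 34.1 in control ears, and its fold was 3.61 with a pseudocount of 64.

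Among immediate early genes, 13 of 23 rose and 2 fell (13 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.000274, and 0.344 with an estimated correlation), with the AP-1 subunit Fosl1 at 2.43 ± 0.30 and Ier5 at 1.42 ± 0.18. Among sebaceous and lipid synthesis genes, 2 of 23 rose and 17 fell (2 rose and 17 fell adjusted over the list alone, camera adjusted p = 0.000274, and 0.371 with an estimated correlation), with the fatty acid elongase Elovl6 at -1.33 ± 0.17 and the squalene epoxidase Sqle at -0.81 ± 0.13. Among heat shock genes, 8 of 13 rose and 1 fell (8 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0228, and 0.197 with an estimated correlation), with Hsp90aa1 at 1.21 ± 0.15 and Hsph1 at 0.88 ± 0.12. Among interferon-stimulated genes, 7 of 12 rose and 0 fell (7 rose and 0 fell adjusted over the list alone, camera adjusted p = 0.0429, and 0.496 with an estimated correlation), with the antiviral gene Rsad2 at 1.22 ± 0.20. Without rescaling, the median of all array A log2 folds was −0.52, Hsph1 lost its call, and the medians of the heat shock (−0.31) and interferon-stimulated (−0.13) lists turned negative while staying above it. Quantile normalization ended the heat shock call (adjusted p = 0.0676). The interferon call was lost without mustard ears 5 and 37 (adjusted p = 0.146), with the animal as a fixed block (0.0824) and with the mean over the probe sets of a gene (0.0509), and the cytokine call without these ears (0.0651).

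The other 25 lists had camera adjusted p from 0.0639 to 0.981, and several held called members in both directions. With the animal as a fixed block and the preset correlation 5 of them were called: proliferation (adjusted p = 0.00215) and hair follicle (0.0194) lower, and macrophage (0.0194), ER stress (0.0226) and acute phase (0.0281) higher. With the mean over the probe sets of a gene the adipocyte list was called lower (camera adjusted p = 0.0363). Of 27 epidermal differentiation genes, 10 rose, including the filaggrin family member Rptn at 2.91 ± 0.30, and 6 fell, including filaggrin itself (Flg) at -0.90 ± 0.15. Of 14 basal keratinocyte genes, 4 rose and 7 fell, with Krt15 at -1.26 ± 0.17 and Dst at -1.15 ± 0.18. In proliferation, 1 of 21 rose and 9 fell: the mitotic cyclin Ccnb2 stood at -2.02 ± 0.23 and Mki67 at -1.41 ± 0.24. In matrix remodelling, 6 of 17 rose and 4 fell, with the stromelysin Mmp10 at 3.53 ± 0.44 and the protease inhibitor Timp1 at 1.70 ± 0.25. In acute phase and coagulation, 5 of 12 rose and 2 fell, with Saa3 at 2.33 ± 0.32 and tissue factor (F3) at -1.79 ± 0.26. In the eicosanoid list, 3 of 18 rose and 7 fell, with the epidermal lipoxygenase Alox12e at -1.79 ± 0.29, the phospholipase Pla2g4a at -1.02 ± 0.17 and the cyclooxygenase Ptgs2 at 0.98 ± 0.22, whose call was lost without rescaling and with the animal as a fixed block. Of macrophage markers, 5 of 14 rose and 0 fell, with the lectin Clec7a at 2.01 ± 0.28. Mmp10, Saa3 and Ptgs2 in control ears and Ccnb2 in mustard ears had mean scaled signals under 100. With a pseudocount of 64 they stood at 2.65, 1.86, 0.68 and −1.44.

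In Nrf2 and oxidative stress, 6 of 15 rose and 4 fell, with Nqo1 at 1.04 ± 0.12 and Gstm1 at -0.89 ± 0.12. Of aryl hydrocarbon receptor targets, 2 of 6 rose and 4 fell. In ER stress and amino acid response, 9 of 20 rose and 4 fell, with Sesn2 at 1.50 ± 0.14. In glycolysis and hypoxia, 7 of 18 rose and 4 fell. In metallothioneins and metal transport, 2 of 8 rose and 3 fell, with the iron exporter Slc40a1 at -1.68 ± 0.21; the median of that list was 0.01 and its mean -0.45. Of antigen-presenting and Langerhans cell genes, 0 of 10 rose and 4 fell, with the class II gene H2-Aa at -1.04 ± 0.18. Of adipocyte genes, 0 of 9 rose and 5 fell, and of endothelial activation genes 2 of 6 rose and 0 fell, with Icam1 at 2.00 ± 0.18 and Procr at 2.32 ± 0.28 (1.93 with a pseudocount of 64). Of hair follicle genes, 0 of 25 rose and 5 fell, with Gata3 at -1.36 ± 0.18. Counts were near 0 elsewhere: 1 of 14 rose and 1 fell of endothelium, 1 of 18 rose and 1 fell of fibroblast and collagen genes, 1 of 7 rose and 1 fell of vanilloid and neurogenic genes, 0 of 13 rose and 1 fell of cartilage, 0 of 7 rose and 1 fell of Schwann cell and nerve markers. Of T cell markers, 0 of 5 rose and 1 fell, and of melanocyte markers 0 of 7 rose and 1 fell; both lists had a positive median (0.14 and 0.05) and a negative mean (-0.11 and -0.07), and camera gave the first as higher and the second as lower. None of the 9 mast cell or 23 skeletal muscle genes was called by limma.

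On array A, 6825 of 15953 probe sets differed between mustard and methylene chloride ears, 3085 higher and 3740 lower, and 333 rose and 513 fell by at least 2-fold. Without rescaling 10715 differed, 271 higher and 10444 lower. On array B, 4491 of 17287 differed, 2220 higher and 2271 lower, with 411 rises and 680 falls of at least 2-fold; the median of all its log2 folds was 0.14. Array B added rises of Stfa2l1 (6.22 ± 0.60), Lce3f (5.30 ± 0.52) and Idi2 (4.09 ± 0.52), and the noradrenaline transporter Slc6a2 (-3.51 ± 0.41), Atp10b (-3.21 ± 0.43) and Agap1 (-2.99 ± 0.31) among its falls. The mean scaled signal of Idi2 was 56.3 in control ears, and its fold was 3.25 with a pseudocount of 64. Signs of RNA quality moved with the group: the mustard ears of animals 5 and 37 had trimmed mean signals of 85.7 and 66.3 and log2 ratios of 3' to 5' Gapdh probe sets of 0.63 and 0.78, against −0.06 ± 0.13 (SD) in the 21 control ears. Without these 2 ears the counts were 3968 on array A and 1770 on array B. They were 4247 and 1747 with the Gapdh ratio as a covariate, and 4006 and 1565 with the animal as a fixed block over complete pairs.

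**Figure D1:**
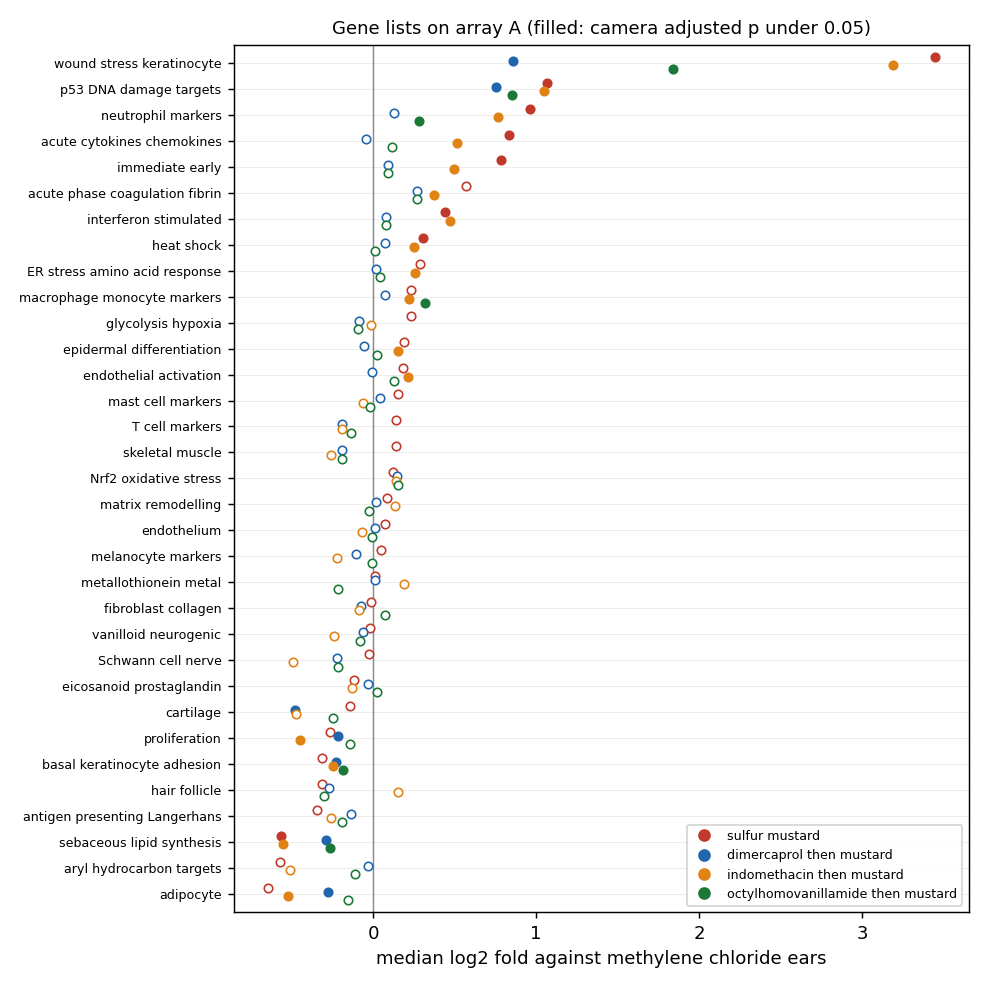
Median log2 fold of each of 33 gene lists against methylene chloride ears on array A (x axis, log2) for mustard alone and after each of the 3 drugs; filled symbols are camera calls at an adjusted p under 0.05 with a preset correlation. Wound and stress keratinocyte genes stood at 3.45 with mustard alone, 0.86 with dimercaprol, 3.19 with indomethacin and 1.84 with octylhomovanillamide.

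The comparison of dimercaprol-pretreated ears with mustard ears asked how far the pretreatment changed the response. Mustard ears are labelled without a pretreatment, so here and for the other drugs the drug and its ethanol are compared together. The largest falls after dimercaprol included chemokines, calprotectin genes and keratinocyte genes. S100a8 and S100a9 were lower by a log2 fold of -3.97 ± 0.65 and -3.82 ± 0.64 (SE; 6 and 5 ears; adjusted p = 3.02e-05 for S100a8). Cxcl2 stood at -3.85 ± 0.64, Cxcl1 at -3.64 ± 0.60, Krt6b at -3.72 ± 0.74, Mmp10 at -3.61 ± 0.53, Sprr2f at -3.28 ± 0.60 and the epidermal growth factor family ligand Epgn at -3.82 ± 0.56. Mt4 was higher by 2.78 ± 0.41 (adjusted p = 1.21e-05), Mycl by 2.73 ± 0.43, Slc6a4 by 2.55 ± 0.38, Dkk2 by 2.37 ± 0.30, Clca3a2 by 2.10 ± 0.35, Serpinb7 by 2.04 ± 0.30, Chst15 by 2.03 ± 0.33 and Dym by 2.02 ± 0.33.

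After dimercaprol 6 of the 33 lists were called against mustard alone, all lower and none with an estimated correlation. Of wound and stress keratinocyte genes, 0 of 19 rose and 16 fell (0 rose and 16 fell adjusted over the list alone, camera adjusted p = 2.52e-11, and 0.356 with an estimated correlation), with Krt6a at -2.38 ± 0.38. Of neutrophil markers, 0 of 13 rose and 7 fell (0 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.000172, and 0.356 with an estimated correlation), with Clec4d at -1.81 ± 0.34. Of immediate early genes, 1 of 23 rose and 11 fell (1 rose and 13 fell adjusted over the list alone, camera adjusted p = 0.000172, and 0.386 with an estimated correlation), with Fosl1 at -1.97 ± 0.37 and Ier3 at -1.22 ± 0.21. Of p53 targets, 2 of 23 rose and 10 fell (2 rose and 11 fell adjusted over the list alone, camera adjusted p = 0.0017, and 0.386 with an estimated correlation), with Cdkn1a at -1.15 ± 0.17 and Mdm2 at -1.08 ± 0.23. Of acute cytokines and chemokines, 1 of 12 rose and 7 fell (1 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.0112, and 0.386 with an estimated correlation), with Il1b at -2.48 ± 0.38. Of glycolysis and hypoxia genes, 0 of 18 rose and 7 fell (1 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.0455, and 0.392 with an estimated correlation), with the growth factor Vegfa at -0.84 ± 0.20. Without rescaling, where the median of all log2 folds was 0.76, the medians of the immediate early, p53 and glycolysis lists were 0.22, 0.45 and 0.49, so they were lower there only relative to all genes. Vegfa turned to 0.0169 (adjusted p = 0.929) in that setting, and Cdkn1a, Mdm2 and Ier3 lost their calls. The glycolysis call was lost with quantile normalization (adjusted p = 0.0912), and the glycolysis and cytokine calls without mustard ears 5 and 37 (0.0656 for both). Heat shock was called lower without these ears (0.0294) and with the mean over the probe sets of a gene (0.0298).

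On array A, 4280 probe sets differed between dimercaprol-pretreated and mustard ears, 2488 higher and 1792 lower. Without rescaling 13232 differed, 13171 higher and 61 lower. On array B, 2844 differed, 1619 higher and 1225 lower, among them Atp10b (3.32 ± 0.52), Slc6a2 (2.68 ± 0.49) and the chemokine Cxcl3 (-3.92 ± 0.65). The counts fell to 1417 and 738 without mustard ears 5 and 37, to 1741 and 512 with the Gapdh ratio as a covariate, and on array B to 1606 without mustard ear 37 alone. With array brightness as a covariate they were 327 and 447, and Cxcl1, Krt6b, Sprr2f, Fosl1, Clec4d and Vegfa were no longer called, at 0.391 to 0.679 of their log2 folds. Cxcl2 and Mmp10 after dimercaprol, Cxcl3 after dimercaprol (scaled signal 42.4) and Slc6a4, Dkk2, Chst15 and Dym with mustard alone had mean scaled signals under 100, so their folds depend on the pseudocount. With 64 Cxcl3 stood at −3.09, Mmp10 at −2.70 and Dkk2 at 1.54.

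Indomethacin pretreatment asked whether blocking cyclooxygenases changed the response. Most of the mustard-induced genes had no called difference: Krt6b stood at -0.28 ± 0.74, S100a8 at -0.10 ± 0.65, Cdkn1a at -0.42 ± 0.17, Cxcl1 at -0.89 ± 0.60 and Ptgs2 itself at -0.06 ± 0.26. Il1b was lower by -1.37 ± 0.38 (SE; 6 and 5 ears; adjusted p = 0.0489), the mucin-type glycoprotein Pdpn by -1.02 ± 0.23 and the nucleic acid sensor Sting1 by -0.82 ± 0.21. Also lower were Knstrn (-1.08 ± 0.27), Zdhhc14 (-0.90 ± 0.20), Leng8 (-0.85 ± 0.22), Ier5l (-0.84 ± 0.20) and Tsks (-0.76 ± 0.21). Higher were the epidermal transcription factor Sp6 (1.89 ± 0.43), the keratinocyte nuclease Dnase1l2 (1.70 ± 0.41), Serpinb7 (1.37 ± 0.30), the ferritin receptor Scara5 (1.27 ± 0.32) and the interferon-induced GTPase Gbp2 (1.01 ± 0.24). One gene list was called, skeletal muscle, with a median of -0.38 and 0 of its 23 members called (camera adjusted p = 0.0367, and 0.974 with an estimated correlation). With quantile normalization that call was lost (adjusted p = 0.0683) and epidermal differentiation was called higher instead (adjusted p = 7.7e-08). The lists called without mustard ears 5 and 37 numbered 6, 3 higher and 3 lower, and 0 with an estimated correlation.

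On array A, 287 probe sets differed between indomethacin-pretreated and mustard ears, 183 higher and 104 lower, with 3098 at an unadjusted p under 0.05 in limma. Without rescaling 5294 differed, 5291 higher and 3 lower. In that setting 7 of the 13 array A genes named as called lost their calls, at 0.266 to 0.430 of their log2 folds. On array B, 547 differed, 413 higher and 134 lower, including the kinase Frk (1.97 ± 0.40), Prima1 (-1.75 ± 0.44) and Ankrd44 (-1.69 ± 0.38). These counts moved with single ears, and each of the 13 array A genes named as called lost its call without mustard ear 5 or 37 or indomethacin ear 17. The median share of the log2 fold they kept was 0.972, 0.869 and 1.00 in these fits, so that calls lost without 1 ear do not show that this ear carried the changes. Without both mustard ears the median share was 0.714, from 0.399 for Il1b to 1.08. Much of the Il1b difference therefore went with these mustard ears. Without mustard ear 5 or 37 the array A count was 0, and without mustard ears 1, 3 and 36 it was 926, 167 and 1220. Without indomethacin ears 17, 18, 19 and 21 it was 15, 76, 11 and 44. On array B it was 150 without mustard ear 5, 46 without 37, 1217 without 36 and 206 without indomethacin ear 18. Prima1 lost its call without mustard ear 5 or 37 or indomethacin ear 16 (largest adjusted p = 0.121), and Ankrd44 without mustard ear 37 (adjusted p = 0.0572). Frk, Prima1 and Ankrd44 all lost their calls with the Gapdh ratio, with array brightness and without mustard ears 5 and 37 (Frk: adjusted p = 0.272, 0.369 and 0.370), while keeping 0.777 to 1.00 of their log2 folds. Sp6 and Frk with mustard alone and Knstrn and Prima1 after indomethacin had mean scaled signals under 100, and with a pseudocount of 64 they stood at 1.21, 1.29, −0.74 and −1.06. With the Gapdh ratio as a covariate the counts were 0 and 1, and with the animal as a random block the array A count was 71.

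Octylhomovanillamide pretreatment asked whether a vanilloid drug changed the response. Among the genes with the largest falls against mustard alone, Cxcl2 changed by -3.04 ± 0.67 (SE; 5 and 5 ears; adjusted p = 0.00237), Mmp10 by -2.77 ± 0.56, Cxcl1 by -2.61 ± 0.63, Sprr2f by -2.43 ± 0.63, S100a9 by -2.22 ± 0.67, S100a8 by -2.18 ± 0.67, Epgn by -2.21 ± 0.59 and the tubulin Tubb6 by -2.09 ± 0.55. Krt6b, at -1.68 ± 0.77 (adjusted p = 0.127), was not called. Mycl was higher by 2.54 ± 0.45, Mt4 by 2.44 ± 0.43, Slc6a4 by 2.31 ± 0.40, Dkk2 by 2.16 ± 0.31, Chst15 by 1.95 ± 0.34, Gas1 by 1.85 ± 0.35, Dym by 1.81 ± 0.34 and Serpinb7 by 1.79 ± 0.32.

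After octylhomovanillamide 8 lists were called against mustard alone, all lower and none with an estimated correlation. Of wound and stress keratinocyte genes, 0 of 19 rose and 11 fell (0 rose and 16 fell adjusted over the list alone, camera adjusted p = 1.18e-08, and 0.282 with an estimated correlation), with Krt17 at -1.74 ± 0.25. Of immediate early genes, 0 of 23 rose and 7 fell (1 rose and 11 fell adjusted over the list alone, camera adjusted p = 0.00034, and 0.369 with an estimated correlation), with Ier3 at -1.11 ± 0.22. Of p53 targets, 2 of 23 rose and 8 fell (2 rose and 12 fell adjusted over the list alone, camera adjusted p = 0.000527, and 0.282 with an estimated correlation), with Plk2 at -1.07 ± 0.22. Of neutrophil markers, 0 of 13 rose and 7 fell (0 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.00141, and 0.282 with an estimated correlation), with Csf3r, the receptor of granulocyte colony-stimulating factor, at -1.35 ± 0.37. Of acute cytokines and chemokines, 0 of 12 rose and 6 fell (0 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.00155, and 0.282 with an estimated correlation), with Il1b at -2.02 ± 0.39. Of heat shock genes, 0 of 13 rose and 3 fell (0 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.0175, and 0.282 with an estimated correlation). Of glycolysis and hypoxia genes, 1 of 18 rose and 5 fell (1 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.0278, and 0.389 with an estimated correlation). Of interferon-stimulated genes, 0 of 12 rose and 3 fell (0 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.0278, and 0.425 with an estimated correlation). Without rescaling, where the median of all log2 folds was 0.63, the medians of all these lists except the wound list were positive, from 0.03 (cytokines) to 0.39 (heat shock). In that setting 3 of the 21 array A genes named as called lost their calls, at 0.305 to 0.403 of their log2 folds. Quantile normalization ended the heat shock (adjusted p = 0.118) and glycolysis (0.0594) calls and added sebaceous and lipid synthesis genes as higher (0.00685). The glycolysis (0.0602) and interferon (0.221) calls were lost without mustard ears 5 and 37, and with the mean over the probe sets of a gene skeletal muscle was called lower (0.0488).

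On array A, 2723 probe sets differed between octylhomovanillamide-pretreated and mustard ears, 1668 higher and 1055 lower, and on array B 1650, with 1131 higher and 519 lower, including Cxcl3 (-3.35 ± 0.68) and Agap1 (2.71 ± 0.39). Without rescaling the array A count was 10844, with 10804 higher and 40 lower. The counts also moved with few ears. Without mustard ears 5 and 37 together they were 79 and 108, and 16 of the 21 array A genes named above as called lost their call while keeping a median of 0.779 of their log2 folds (0.592 to 0.930). With the Gapdh ratio as a covariate the counts were 26 and 35, and with array brightness 15 and 34, and in each of these settings 19 of the 21 lost their call, with medians of 0.732 and 0.765 of the log2 fold kept. The array B call of Cxcl3 was lost in all 3 settings (adjusted p = 0.113, 0.120 and 0.131), with 0.714, 0.830 and 0.778 of its log2 fold kept. Mmp10 and Cxcl3 after octylhomovanillamide were under a scaled signal of 100, and with a pseudocount of 64 they stood at −2.16 and −2.73. S100a8 (largest adjusted p = 0.0976) lost its call without mustard ear 5 or 37 or octylhomovanillamide ear 28 or 33, and S100a9 (0.0845) also without mustard ear 3. On array A the count was 1668 without mustard ear 5, 1430 without 37, 4136 without 36 and 1759 without octylhomovanillamide ear 28. On array B it was 1044, 680 and 2652 without mustard ears 5, 37 and 36, and 945 without octylhomovanillamide ear 30.

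**Figure D2:**
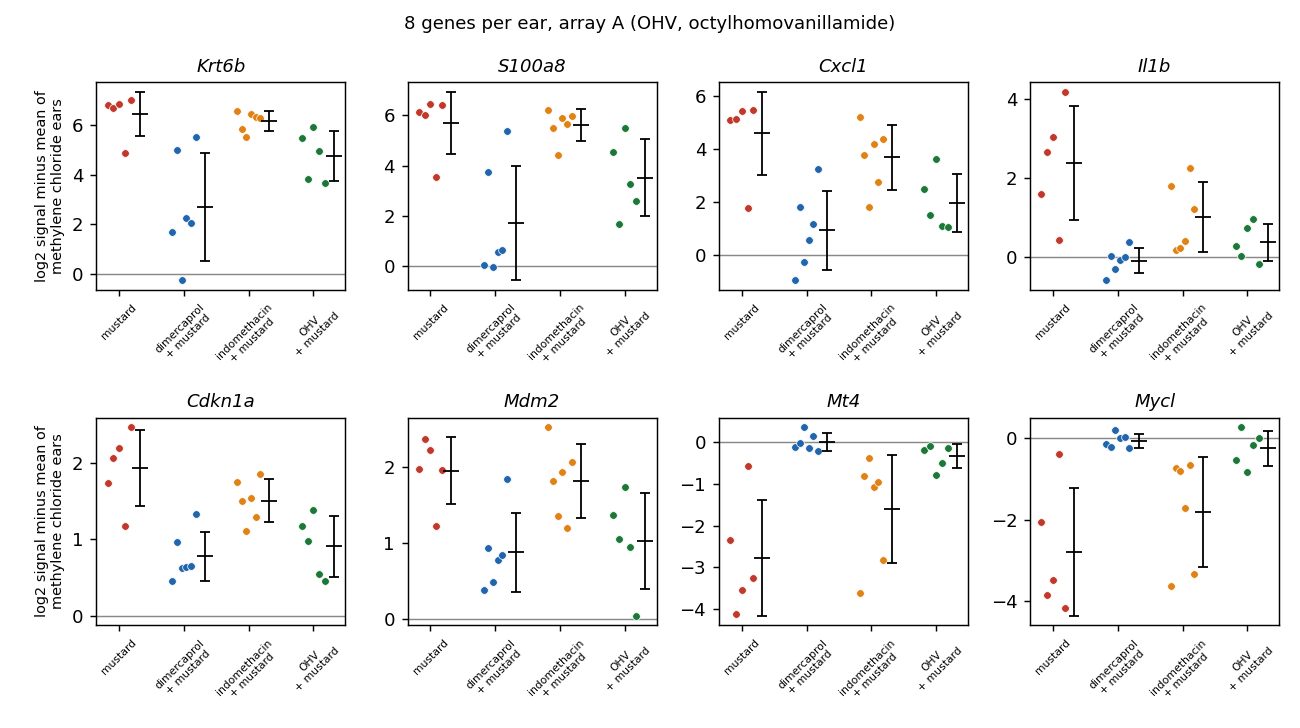
Log2 signal minus the methylene chloride mean (y axis) of 8 genes in each mustard and drug-then-mustard ear on array A. Points are ears, bars are group means with SD, and the horizontal line is the methylene chloride mean. Mustard ear 36 had the lowest S100a8 of the 5 mustard ears, at a log2 signal of 11.41 against 13.87 to 14.32 in the others.

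A score of the mustard response, from probe sets changed at least 2-fold, measured how much of it was left in each pretreated ear. In percent of the mustard mean, the score was 29.1 ± 18.7 (SD, n = 6) after dimercaprol, 40.0 ± 20.1 (n = 5) after octylhomovanillamide and 83.6 ± 25.2 (n = 6) after indomethacin. Methylene chloride ears stood at 0.20 ± 4.46 (n = 21), near 0 by construction, since the score is centred on their mean. Unlike mustard ears, they were not held out of the signature as a rule, so their spread may be too small. The difference from mustard ears was −0.969 on the log2 scale for dimercaprol (2-sided exact permutation p = 0.00866, adjusted over the 3 drugs 0.0260), with 6 of 6 ears below the mustard mean. It was −0.820 for octylhomovanillamide (exact p = 0.0238, adjusted 0.0357; 5 of 5 ears) and −0.225 for indomethacin (exact p = 0.413, adjusted 0.413; 4 of 6 ears). The 5 mustard ears ranged from 34.2 in animal 36 to 128 in animal 37. The octylhomovanillamide call was lost in 7 of 10 fits without 1 ear (largest adjusted p = 0.0833), the dimercaprol call in 0 of 11. With log2 array brightness as a second term the differences were −0.345 (SE 0.328) for dimercaprol and −0.521 (SE 0.394) for octylhomovanillamide, each less than 2 SE from 0. Without mustard ears 5 and 37 neither adjusted p was under 0.05: the differences were −0.818 (exact p = 0.0357, adjusted 0.107) for dimercaprol and −0.646 (exact p = 0.125, adjusted 0.188) for octylhomovanillamide.

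**Figure D3:**
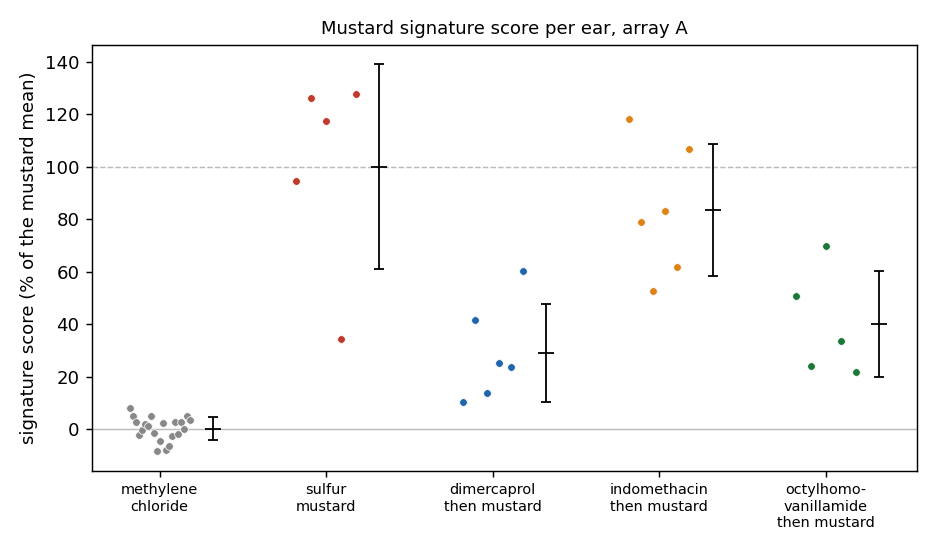
Mustard signature score of each ear in percent of the mustard mean (y axis), by group, with group mean and SD. Dimercaprol ears ran from 10.3 to 60.1, octylhomovanillamide ears from 21.7 to 69.6, indomethacin ears from 52.7 to 118 and mustard ears from 34.2 to 128.

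Against methylene chloride ears, pretreated ears showed how much expression was still displaced. After dimercaprol the RNA of p53 targets was still raised: 15 of 23 rose and 1 fell (17 rose and 1 fell adjusted over the list alone, camera adjusted p = 5.66e-25, and 2.91e-05 with an estimated correlation), with Ccng1 at 1.28 ± 0.13, the epoxide hydrolase Ephx1 at 1.13 ± 0.09, the nuclease Aen at 1.10 ± 0.12 and Mdm2 at 0.87 ± 0.18 (SE; 6 and 21 ears). Wound genes were raised too, 9 of 19 rose and 0 fell (12 rose and 0 fell adjusted over the list alone, camera adjusted p = 6.28e-13, and 0.172 with an estimated correlation), with Krt6b at 2.71 ± 0.57 and Krt16 at 2.46 ± 0.43. Ears differed in this: the mean rise of the wound list was 1.98 and 2.37 in dimercaprol ears 8 and 12. It was 0.436, 0.527, 0.840 and 0.942 in ears 6, 9, 10 and 11, where the highest methylene chloride ear, 19, stood at 0.860. Il1b stood at -0.10 ± 0.29 and Cxcl2 at -0.27 ± 0.49, without a call, and the melanoma adhesion molecule Mcam rose by 2.67 ± 0.30. Of sebaceous and lipid genes, 0 of 23 rose and 6 fell (0 rose and 16 fell adjusted over the list alone, camera adjusted p = 1.79e-12, and 0.0732 with an estimated correlation), with Elovl6 at -0.91 ± 0.16. Elastin (Eln) stood at -1.20 ± 0.33, the cadherin Cdh13 at -0.98 ± 0.15 and the centromere protein Cenpa at -0.97 ± 0.18. Basal keratinocyte (camera adjusted p = 0.000212, and 0.258 with an estimated correlation), cartilage (camera adjusted p = 0.00188, and 0.558 with an estimated correlation), adipocyte (camera adjusted p = 0.00786, and 0.529 with an estimated correlation) and proliferation (camera adjusted p = 0.00877, and 0.558 with an estimated correlation) lists were called lower. In all, 487 probe sets differed, 291 higher and 196 lower, and without rescaling 383 were higher and 5 lower. Of the 11 genes named as called, 3 lost their calls without rescaling, at 0.616 to 0.759 of their log2 folds. Without a filter 1 lost its call, and 1 with array brightness as a covariate. The count was 273 without dimercaprol ear 8, 188 without ear 12 and 23 with the animal as a fixed block, where Mdm2, Krt6b, Krt16, Elovl6, Eln, Cdh13 and Cenpa were no longer called although they kept 0.757 to 1.06 of their log2 folds (Cenpa −0.97, Elovl6 −0.92, Krt16 2.11). With the preset correlation the block also added calls of 5 lists, among them skeletal muscle (adjusted p = 3.1e-11) and Schwann cell genes (0.00118), both lower. Eln also lost its call without dimercaprol ear 6, 9, 10, 11 or 12 (largest adjusted p = 0.126).

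After indomethacin the pretreated ears differed from methylene chloride ears at 5726 probe sets, 2595 higher and 3131 lower. Without rescaling the count was 2558, with 815 higher and 1743 lower. Defb3 rose by 7.08 ± 0.55 (5.77 with a pseudocount of 64), Krt6b by 6.15 ± 0.57, S100a8 by 5.60 ± 0.49 and Cxcl1 by 3.68 ± 0.46 (SE; 6 and 21 ears), while Mki67 changed by -1.73 ± 0.23 and Gas1 by -1.89 ± 0.26. Cxcl1 stood at 2.75 with a pseudocount of 64. The circadian output genes Dbp and Hlf stood at -2.00 ± 0.28 and -1.98 ± 0.27. Of the 33 lists 16 were called, and wound (18 of 19 rose and 0 fell; camera adjusted p = 1.19e-20, and 0.0408 with an estimated correlation) and p53 (17 of 23 rose and 3 fell; camera adjusted p = 5.98e-14, and 0.00353 with an estimated correlation) calls held with an estimated correlation. The other 14 did not: their smallest adjusted p was 0.134 (heat shock) with an estimated correlation and their largest 0.532 (macrophage). With the animal as a fixed block 3033 probe sets differed and 8 lists were called.

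After octylhomovanillamide 441 probe sets differed from methylene chloride ears, 290 higher and 151 lower. Without rescaling the count was 132, with 127 higher and 5 lower. Of p53 targets, 14 of 23 rose and 0 fell (16 rose and 2 fell adjusted over the list alone, camera adjusted p = 4.19e-23, and 5.94e-05 with an estimated correlation), with Ccng1 at 1.31 ± 0.14, Aen at 1.22 ± 0.12 and the polymerase Polk at 1.10 ± 0.13 (SE; 5 and 21 ears). Of wound genes, 12 of 19 rose and 0 fell (14 rose and 0 fell adjusted over the list alone, camera adjusted p = 5.17e-22, and 0.0325 with an estimated correlation), with Defb3 at 4.80 ± 0.59 (3.58 with a pseudocount of 64) and Krt6b at 4.76 ± 0.61. S100a8 rose by 3.52 ± 0.53 and Cxcl1 by 1.96 ± 0.49 (1.28 with a pseudocount of 64). Fhit stood at -1.50 ± 0.26, Igfbp3 at -1.27 ± 0.20 and Mycn at -1.40 ± 0.40. The sebaceous (camera adjusted p = 7.59e-08, and 0.25 with an estimated correlation), basal keratinocyte (camera adjusted p = 0.000376, and 0.313 with an estimated correlation), neutrophil (camera adjusted p = 0.00337, and 0.313 with an estimated correlation) and macrophage (camera adjusted p = 0.0118, and 0.568 with an estimated correlation) lists were called without holding. The count was 240, 155 and 290 without octylhomovanillamide ears 27, 29 and 30, and 167 with the animal as a fixed block. Cxcl1 lost its call there and without octylhomovanillamide ear 27 or 29 (1.61 with the block; largest adjusted p without an ear = 0.215), and Mycn there, with a pseudocount of 64 (adjusted p = 0.0582) and in 9 of 26 fits without 1 ear, among them those without each of the 5 octylhomovanillamide ears (largest adjusted p = 0.178). With the preset correlation the block added calls of immediate early genes (higher, adjusted p = 0.00287) and of antigen-presenting and hair follicle genes (lower, 0.00393 for both).

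Ears given a drug without mustard asked what each drug did by itself. No probe set passed the limma test against ethanol after dimercaprol, indomethacin or octylhomovanillamide, with 773, 1117 and 996 at an unadjusted p under 0.05 and 797.65 given by chance. After octylhomovanillamide the inner root sheath keratin Krt27 stood at 2.54 ± 0.92 and trichohyalin (Tchh) at 2.35 ± 1.07 (SE; 5 and 3 ears), without a call. Some lists were called, none with an estimated correlation and none with a called member. After dimercaprol the fibroblast list was lower (camera adjusted p = 0.00403, and 0.691 with an estimated correlation), and hair follicle (camera adjusted p = 0.00403, and 0.691 with an estimated correlation) and proliferation (camera adjusted p = 1.34e-12, and 0.601 with an estimated correlation) lists were higher. After octylhomovanillamide antigen-presenting (camera adjusted p = 0.00114, and 0.337 with an estimated correlation), basal keratinocyte (camera adjusted p = 0.0007, and 0.6 with an estimated correlation), epidermal differentiation (camera adjusted p = 0.000276, and 0.6 with an estimated correlation) and wound (camera adjusted p = 0.0104, and 0.655 with an estimated correlation) lists were lower, and hair follicle (camera adjusted p = 3.26e-05, and 0.6 with an estimated correlation) and proliferation (camera adjusted p = 7.3e-05, and 0.6 with an estimated correlation) lists were higher. After indomethacin none was called. All 3 drugs were compared with the same 3 ethanol ears. Against naive ears, as given below, these ethanol ears had lower hair follicle and proliferation lists and a higher antigen-presenting list. The opposite calls of these lists after dimercaprol or octylhomovanillamide are therefore not independent of each other. They cannot be told apart from a shift of the ethanol ears. With quantile normalization skeletal muscle was called higher after indomethacin (adjusted p = 0.0204) and octylhomovanillamide (0.0223), and the epidermal differentiation call after octylhomovanillamide was lost (0.324), as was its wound call with the mean over the probe sets of a gene (0.0571).

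Ethanol ears did not differ from naive ears at any probe set in limma, with 501 at an unadjusted p under 0.05 (3 and 3 animals). Antigen-presenting (camera adjusted p = 0.00388, and 0.38 with an estimated correlation), immediate early (camera adjusted p = 0.0301, and 0.857 with an estimated correlation) and neutrophil (camera adjusted p = 0.043, and 0.695 with an estimated correlation) lists were called higher and hair follicle (camera adjusted p = 0.00622, and 0.857 with an estimated correlation) and proliferation (camera adjusted p = 4.76e-06, and 0.695 with an estimated correlation) lists lower. Methylene chloride ears differed from naive ears at 3432 probe sets, 1181 higher and 2251 lower. Without rescaling 893 differed, and the balance turned to 846 higher and 47 lower. The nuclear RNA Malat1 stood at 3.22 ± 0.57, the kinase Prkcq at 2.29 ± 0.45, the olfactory marker protein Omp at -2.41 ± 0.36 and the hair keratin Krt84 at -1.44 ± 0.25 (SE; 21 ears and 3 animals). All methylene chloride ears came from 1 set of animals and all naive ears from the other, so that set and group cannot be told apart. Prkcq in naive and Omp in methylene chloride ears were under a scaled signal of 100, and with a pseudocount of 64 they stood at 1.48 and −1.83. The count was 1617 without naive animal 502 and 1043 without 503, and with quantile normalization 52.6% of the calls were higher.

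Whether a drug's effect with mustard differed from its effect without was tested as a difference of differences. The control was ethanol ears without mustard, but with mustard it was ears labelled without a pretreatment. For dimercaprol 1373 probe sets passed, 838 higher and 535 lower. They included Mt4 (2.82 ± 0.58), Slc6a4 (2.82 ± 0.56), Scara5 (2.72 ± 0.50), S100a8 (-4.83 ± 1.00), Defb3 (-4.79 ± 1.08), Krt6b (-4.54 ± 1.18) and Epgn (-4.00 ± 0.81). For octylhomovanillamide 295 passed, 216 higher and 79 lower, with Mt4 at 2.60 ± 0.57, Slc6a4 at 2.48 ± 0.55, Mmp10 at -2.92 ± 0.76, Il1b at -2.19 ± 0.54 and Krt17 at -1.65 ± 0.37. Without rescaling 0 passed for octylhomovanillamide, and these 5 genes lost their calls (Mt4 3.01, adjusted p = 0.0845, and Slc6a4 1.97, adjusted p = 0.129). They also lost them without mustard ears 5 and 37, at 0.624 to 0.841 of their log2 values. For indomethacin 6 passed, 3 higher and 3 lower, with Rfx2 at 3.18 ± 0.65 and Zdhhc14 at -1.88 ± 0.35, which lost their calls in 13 and 5 of 18 fits without 1 ear, and also without rescaling, where 0 passed. Krt17 lost its call without ethanol ear 515 (adjusted p = 0.0524) and the dimercaprol call of Krt6b was lost without ethanol ear 520 (adjusted p = 0.0564) and without mustard ears 5 and 37 (−4.21, adjusted p = 0.0643). Mmp10 and Il1b lost theirs in 9 and 6 of 18 such fits (largest adjusted p = 0.0839 and 0.0743). The dimercaprol count was 2516 without mustard ear 36, 788 without 37 and 796 without ethanol ear 520. The octylhomovanillamide count was 458, 106, 110, 1338 and 69 without mustard ears 1, 3, 5, 36 and 37, 70 and 130 without octylhomovanillamide ears 28 and 30, 108 and 153 without ethanol ears 515 and 520, and 182 without drug-alone ear 517. Without mustard ears 5 and 37 the counts were 284, 0 and 0 for dimercaprol, octylhomovanillamide and indomethacin. Gene lists called by this test numbered 7 for dimercaprol, 3 for indomethacin and 11 for octylhomovanillamide, and 0 for each with an estimated correlation.

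Left ears, all given methylene chloride, were compared by the treatment of the right ear to ask whether the opposite ear mattered. The limma F-test passed 6 probe sets, with 1176 at an unadjusted p under 0.05, and the count ran from 2 to 17 when each ear was left out in turn.

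**Figure D4:**
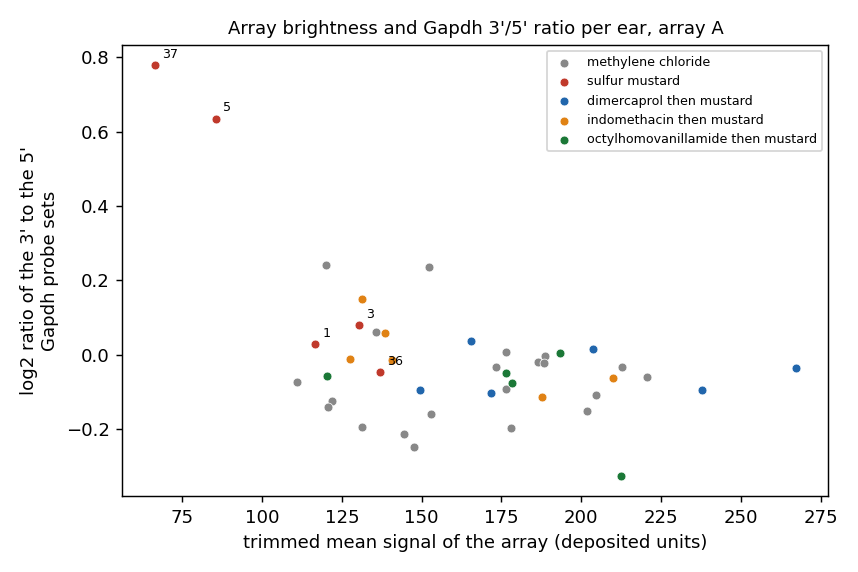
Trimmed mean signal (x axis, deposited units) against the log2 ratio of 3' to 5' Gapdh probe sets (y axis, log2) on array A, by group. Methylene chloride, mustard and drug-then-mustard ears are drawn, with mustard ears numbered. Naive, ethanol and drug-alone ears are not drawn. Mustard ears 5 and 37 had the highest ratios, 0.63 and 0.78.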

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

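The tests below were chosen after the results were seen, except those with array brightness as a second term of the score and the splits of the ears.

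Mustard ears differed from methylene chloride ears by at least 2-fold at 846 probe sets of array A, while mustard ears 5 and 37 had dim arrays and a raised 3' to 5' Gapdh ratio. Without these ears the median ratio of the 846 log2 folds to their original values was 0.864 (quartiles 0.772 to 0.938), with 778 still past the threshold, which argues against 3'-biased RNA of these ears as the whole cause. With array brightness as a covariate it was 0.874 (0.812 to 0.941; 808 past the threshold), and with skeletal muscle content 0.997 (0.989 to 1.01; 846), which argues against both in the same way. The response may therefore be biological, as a hypothesis, although smaller parts of it move with RNA quality. Of 100 splits of the ears into groups of these sizes, 1, the real one, gave as many calls as 6825, and the highest other gave 3722.

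Dimercaprol and octylhomovanillamide ears had lower mustard scores than mustard ears, and their arrays were brighter by 0.92 and 0.74 on the log2 scale. Without mustard ears 5 and 37 the dimercaprol difference was 0.844 of its size (exact p = 0.0357, adjusted 0.107), which argues against these ears as its whole cause, and the octylhomovanillamide difference 0.787 of its size (exact p = 0.125), which stays open. With brightness as a second term the differences were −0.345 (SE 0.328, n = 11) and −0.521 (SE 0.394, n = 10). The first goes with brightness as a candidate cause, and the second cannot be told apart, since brightness and group go together in so few ears. Brightness was measured after exposure. If the response itself dimmed the arrays, the second term would also remove an effect of the pretreatment, so that it cannot decide between them. Brightness also differed between left ears given methylene chloride alone. Their trimmed means were 173, 120, 122 and 111 in mustard animals 1, 3, 36 and 37. They were 186, 188, 221 and 131 in dimercaprol animals 8, 9, 10 and 11, and 144 to 178 in the octylhomovanillamide animals. Some of the brightness difference may thus lie between animals or their arrays, which was not tested. Brightness acting as among the 21 methylene chloride ears would give −0.0771 (SE 0.0388) and −0.0626 (SE 0.0315), far from −0.969 and −0.820. That argues against this form of it only within their trimmed means of 111 to 221. Mustard ears 5 and 37, at 85.7 and 66.3, were dimmer, and the score was centred on the control ears. For such dim arrays the slope cannot decide. A real effect of the drug or of its ethanol stays open beside RNA quality of the mustard ears and differences between the animals of the groups.

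Mustard ear 36 responded less than the other mustard ears. Its log2 signal was far from the others for Tnf (6.29, others 7.33 to 7.66), Cxcl1 (7.30, others 10.60 to 10.98) and S100a8 (11.41, others 13.87 to 14.32), and likewise for S100a9 (10.53, others 13.83 to 14.21), Krt6b (12.58, others 14.38 to 14.73) and Sprr1a (12.51, others 14.34 to 14.58). Its score of 34.2% lay above the highest methylene chloride ear, 8.01% (SD 4.46), which argues against a methylene chloride ear with the wrong label, and left ear 36 scored 0.0450%, which argues against a swap within the animal. Its Gapdh ratio of −0.0453 was within the −0.247 to 0.241 of control ears, which argues against 3'-biased RNA. A lower delivered dose or a difference between animals may remain, and neither was tested.

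Other ears stood apart from their group in single values. Krt10 was 15.24 in mustard ear 1 (others 14.68 to 14.76). The skeletal muscle mean was 10.70 in dimercaprol-then-mustard ear 9 (others 11.55 to 12.06), and Mdm2 was 10.74 in ear 12 of that group (others 9.28 to 9.82). Mmp9 was 8.65 in indomethacin-then-mustard ear 21 (others 7.39 to 7.78). The Gapdh ratio was −0.325 in octylhomovanillamide-then-mustard ear 30 (others −0.0758 to 0.00507). Among ears given a drug alone, Cxcl2 was 6.11 in dimercaprol ear 507 (others 6.89 to 7.04) and Hmox1 was 7.39 in dimercaprol ear 506 (others 9.02 to 9.06). Ptgs2 was 7.61 in indomethacin ear 512 (others 6.96 to 7.04), and Tnf was 5.90 in octylhomovanillamide ear 517 (others 7.40 to 7.65). Of 166 groups of values examined, 15 held such an ear, where chance at 1 in 20 gives 8.3. The 15 include the log2 signals given above for the mustard ear that responded less, which all come from the same ear. The groups of values share ears and are not independent. The count therefore does not show an excess for the other ears named here.

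Drug effects with and without mustard differed, by the test of that difference, at 1373 probe sets for dimercaprol, 6 for indomethacin and 295 for octylhomovanillamide. For dimercaprol 1 of 100 splits gave as many, the real one, and the highest other gave 221, which argues against chance. For indomethacin 11 of 100 did, with a highest other of 105, and for octylhomovanillamide 7 of 100, with a highest other of 1300, so chance cannot be excluded. Splits with several times the real count may point to a structure of the samples, which was not tested. Leaving out mustard ear 36 alone gave 1338 for octylhomovanillamide and 26 for indomethacin. Where the splits with the highest counts placed this ear was not tested.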

How the results depend on the processing

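Array brightness as a covariate, scaling on shared probe sets and leaving out mustard ears 5 and 37 or methylene chloride ear 19 were chosen after seeing the data. Of 172 called values of named genes, 1 reversed: Vegfa, lower after dimercaprol against mustard, stood at 0.0169 (adjusted p = 0.929) without rescaling. All others kept their direction. Calls were lost for 28 without rescaling, 36 of 154 with the Gapdh ratio and 43 of 154 with array brightness as a covariate, 41 of 139 without mustard ears 5 and 37, 10 of 88 with a fixed block, and 0 to 9 in each other setting. Counts of probe sets over 1.5 times from the reported value are given here, and where an alternative does not itself remove ears or probe sets, the cause was not tested. Without rescaling, mustard against methylene chloride gave 10715 on array A (271 higher, 10444 lower), dimercaprol against mustard 13232 (13171 higher, 61 lower), indomethacin against mustard 5294 (array B 3044), octylhomovanillamide against mustard 10844 (array B 4211), indomethacin and octylhomovanillamide against methylene chloride 2558 and 132, methylene chloride against naive 893 (846 higher, 47 lower), the indomethacin and octylhomovanillamide differences of differences 0 and 0, and left ears 10. That setting left brightness in the values, and the median of all log2 folds was −0.52 for mustard against methylene chloride and 0.76, 0.45 and 0.63 for dimercaprol, indomethacin and octylhomovanillamide against mustard. The octylhomovanillamide score difference was −0.822 there (adjusted p = 0.0595), no longer past the threshold.

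With the Gapdh ratio as a covariate, array A and array B counts were 4247 and 1747 for mustard against methylene chloride, 1741 and 512 for dimercaprol, 0 and 1 for indomethacin and 26 and 35 for octylhomovanillamide against mustard. With brightness they were 4441 and 1804, 327 and 447, 0 and 1, and 15 and 34. Without mustard ears 5 and 37 they were 3968 and 1770, 1417 and 738, 0 and 0, and 79 and 108. The differences of differences were then 284, 0 and 0 for dimercaprol, indomethacin and octylhomovanillamide, and the score differences −0.818 for dimercaprol and −0.646 for octylhomovanillamide, neither past the threshold. With the animal as a fixed block over complete pairs, mustard against methylene chloride gave 4006 and 1565, and dimercaprol, indomethacin and octylhomovanillamide against methylene chloride 23, 3033 and 167. For indomethacin against mustard on array A the count was 71 with a random block, 39 with the muscle covariate and 155 without a filter. The indomethacin difference of differences was 10 without a filter and 2 with a stricter one, where methylene chloride against naive gave 1620. Left ears gave 2 without a filter, 2 without trend and 2 without methylene chloride ear 19.

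Numbers of called gene lists with an estimated correlation were 1 for mustard against methylene chloride, 0, 0 and 0 for dimercaprol, indomethacin and octylhomovanillamide against mustard, 1, 2 and 2 against methylene chloride, 0 for dimercaprol alone, 0 for octylhomovanillamide alone, 0 for ethanol and 0, 0 and 0 for the dimercaprol, indomethacin and octylhomovanillamide differences of differences, against 7, 3 and 11 with the preset one. Without mustard ears 5 and 37 they were 6 for indomethacin against mustard, 4 for the dimercaprol and 5 for the octylhomovanillamide difference of differences; with an estimated correlation as well they were 1 for mustard against methylene chloride and 0 for each drug against mustard and each difference of differences. With the fixed block 12 were called for dimercaprol and 8 for indomethacin against methylene chloride, and with quantile normalization 1 for indomethacin alone. For indomethacin against mustard quantile normalization also gave 1, but epidermal differentiation (adjusted p = 7.7e-08) in place of skeletal muscle (adjusted p = 0.0683). It also ended the calls of heat shock for mustard against methylene chloride (adjusted p = 0.0676), of glycolysis for dimercaprol against mustard (0.0912), of glycolysis and heat shock for octylhomovanillamide against mustard (0.0594 and 0.118), of ER stress and macrophage lists for indomethacin against methylene chloride (0.0754 and 0.0533) and of epidermal differentiation for octylhomovanillamide alone (0.324). It added calls of sebaceous genes (higher, 0.00685) for octylhomovanillamide against mustard, epidermal differentiation (higher, 0.0223) for octylhomovanillamide against methylene chloride and skeletal muscle (higher, 0.0223) for octylhomovanillamide alone.

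Leaving out each ear in turn gave 5695 to 7400 for mustard against methylene chloride on array A and 3033 to 5194 on array B, 3018 to 5275 and 1606 to 3776 for dimercaprol against mustard, 0 to 1220 and 46 to 1217 for indomethacin, and 1430 to 4136 and 680 to 2652 for octylhomovanillamide. Against methylene chloride the ranges were 188 to 551, 4570 to 5793 and 155 to 621 for these drugs. They were 0 to 0 for each drug alone and for ethanol, 1043 to 3553 for methylene chloride against naive, 2 to 17 for left ears, and 788 to 2516, 0 to 26 and 69 to 1338 for the dimercaprol, indomethacin and octylhomovanillamide differences of differences. Score differences ran from −1.05 to −0.873 for dimercaprol, −0.374 to −0.140 for indomethacin and −0.922 to −0.722 for octylhomovanillamide. Signal over background limits dim genes: 70.5% of array A and 76.8% of array B probe sets passed the filter, and the others were not tested.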

Other observations

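Tests of the ratio of p53 targets to wound genes and of drugs against each other were chosen after the scores were seen; the splits were chosen before.

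Genes of the p53 response and genes of wounded keratinocytes were set against each other in each ear, as the ratio of their mean rises over methylene chloride ears. The hypothesis was that a drug lowers wound genes more than p53 targets. The ratio was 0.672 ± 0.295 (SD, n = 6) after dimercaprol and 0.338 ± 0.0938 (n = 5) with mustard alone, a difference of 0.333 (2-sided exact permutation p = 0.0433, adjusted over 3 drugs 0.130; 5 of 6 ears above the mustard mean), which fails the correction. The difference was −0.0324 after indomethacin (exact p = 0.578, adjusted 0.722; 2 of 6 ears above) and 0.0263 after octylhomovanillamide (exact p = 0.722, adjusted 0.722; 2 of 5 above). Mustard ear 36, with a weak response and no drug, had a ratio of 0.505 against 0.278 to 0.306 in the other mustard ears, so that a weaker response without a drug may also raise it. The ratios of dimercaprol ears 6, 9 and 10 (1.00, 1.01 and 0.702) rest on small wound rises of 0.436, 0.527 and 0.840. Methylene chloride ear 19 reached 0.860, so that these ratios are unstable.

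Drugs were compared with each other on the mustard score. After dimercaprol it was lower than after indomethacin by a difference of −54.5 percentage points (exact permutation p = 0.00433, adjusted 0.0130), and after octylhomovanillamide by −43.6 (exact p = 0.0173, adjusted 0.0260). Between dimercaprol and octylhomovanillamide the difference was −10.9 (exact p = 0.364, adjusted 0.364), which does not show that they act alike. Doses and volumes differed between the drugs.

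Splits of the same ears into groups of the same sizes, 100 for each comparison with the real one counted, were refitted. For mustard against methylene chloride on array B 1 gave as many calls as the real 4491 (highest other 1513). For dimercaprol against mustard it was 1 on array A (4280, highest other 3557) and 1 on array B (2844, highest other 1639). For octylhomovanillamide against mustard it was 3 (2723, highest other 3455) and 2 (1650, highest other 2211). For indomethacin on array B it was 2 (547, highest other 881). For dimercaprol, indomethacin and octylhomovanillamide against methylene chloride it was 1, 1 and 1 (487, 5726 and 441; highest others 16, 973 and 22), for methylene chloride against naive 1 (3432, highest other 222) and for left ears 2 (6, highest other 13). Left ears apart, such shares argue against chance in these comparisons. For octylhomovanillamide and array B indomethacin against mustard another split nevertheless gave more calls than the real one. For left ears another split also did, and the real count of 6 ran from 2 to 17 when each ear was left out. The shares were not adjusted over the comparisons, so chance cannot be excluded for left ears. For indomethacin against mustard on array A 8 of 100 gave as many as 287 (highest other 1237), so chance cannot be excluded, and that highest count, several times the real one, may point to a structure of the samples, which was not tested. Leaving out mustard ear 36 alone gave 1220, and where that split placed this ear was not tested either.

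No drug-alone comparison had a call, so that each of the 35 splits for dimercaprol, 35 for indomethacin and 56 for octylhomovanillamide gives at least the real 0 by construction and tests nothing (highest others 6, 5 and 75). For ethanol against naive 10 splits of the 3 and 3 animals are too few for a share under 0.05; the real count was 0 and the highest other 0. Splits that exchanged ears within the same number of pairs kept each paired animal in both groups. Any remaining treated ear was drawn from the animals with a single ear in the comparison. As many calls as the real split were given by 1 of 100 for mustard against methylene chloride on array A (highest other 6368) and 1 of 100 on array B (3183). Against methylene chloride it was 1 of 100 for dimercaprol (216), 1 of 100 for indomethacin (2816) and 1 of 32 for octylhomovanillamide (389).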
